A study of Mus musculus with 2 samples.

How the data were processed

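Gene expression was measured on whole-transcript GeneChip arrays in mouse macrophages grown from bone marrow. Per the labels' protocols, marrow cells were cultured in medium with 10% fetal bovine serum, M-CSF, the growth factor that drives macrophage differentiation, was given at the start (day 0) and again on day 3 at a dose of 25 ng/mL, and cells were used from day 5. Total RNA was extracted with Trizol and labelled with biotin by a whole-transcript kit, per the labels' protocols. There were 2 samples in 2 groups, 1 array per group: cells of the genotype given as LysM (+);MC4RTB/TB, called LysM(+) here, and cells of the genotype given as MC4RTB/TB, called TB/TB here. The groups were taken from the genotype label.

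The deposited values are log2 expression values per probe set that the authors made with RMA (robust multi-array average), which corrects background, normalizes between arrays and summarises probes, using Affymetrix Expression Console, per the submitters' processing notes. Versions are not given in the sources used here. The log base is not given in the sources used here and was taken as 2 from the method's name. The values ran from 2.71 to 19.5 on the LysM(+) array and from 2.57 to 19.5 on the TB/TB array, an upper end higher than is usual for RMA, so a further transformation is not excluded; every fold given depends on this reading, while the direction of a single gene does not. The sorted values of the columns differed by at most 0.16, so the value distributions had already been matched closely. No detection calls or scanner intensities were used here, so the signal over background of a probe set is not known beyond the 23 background control probe sets, whose values lay between 3.09 and 6.81 and differed between the arrays by at most 0.09.

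Of 28846 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several, 94 were control probe sets and 9180 had no gene name here. All 19572 named probe sets were matched by Entrez ID to the RefSeq gene table of GRCm38.p6, used for symbols and chromosomes only. They covered 19505 genes, of which 55 had more than 1 probe set, and a gene's value was the mean of its probe sets. A group of 39 genes had both values equal to those of another gene; these were taken to share probes and cannot be told apart.

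With 1 array per group there is no replicate error, so no test was run and no p-value, standard error or confidence interval across samples was computed. All differences are LysM(+) minus TB/TB on the log2 scale and describe these 2 arrays. The following choices were made before the data were examined. A gene was counted as differing when its values were at least 1.5-fold apart and its brighter value reached the median of the named probe sets' 2-array means, a log2 value of 6.12, called the brightness floor. A total of 48 gene lists were fixed, naming 844 genes, of which 723 were measured. The median difference of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart when its percentile was under 2.5 or over 97.5. The percentile describes these arrays and is not a p-value. Lists with fewer than 5 measured members were given no percentile, a limit set with the data at hand, which left 47 lists. Members of a list are regulated together, so lists stand apart more often than the 2.35 of 47 that independent genes would give. A single gene's difference was also ranked among the 500 genes nearest in mean value. The genes named are Mc4r, Lyz2 and the other melanocortin receptors; the 15 genes with the largest difference in each direction among those counted, leaving out predicted genes, olfactory and vomeronasal receptors and immunoglobulin and T-cell receptor segments; the 4 members of each list standing apart that differed most in its direction; and up to 4 counted members of every other list. Other genes are said to have been chosen after their values were seen.

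The procedure was tested on simulated data for the LysM(+) and TB/TB comparison over 19505 genes, with noise set to the observed spread between the arrays. Of the genes given a 4-fold change 100% were counted, of those given a 2-fold change 70.1%, of those given a 1.5-fold change 55.2%, and of 9556 unchanged genes 12.5%. Of 100 lists of 20 genes shifted by 0.3 on the log2 scale, 84% stood apart, and of 100 unshifted lists 2% did. Noise was drawn separately for each gene, so these shares do not hold for lists whose members are regulated together. The observed spread can include true differences, but the simulated noise was normal and may hold fewer large differences than array-to-array noise does. It was therefore not shown to be an upper setting, and the share of unchanged genes counted is not an upper limit.

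The alternatives tried were centring on the median difference, quantile normalization of the columns, loess of the difference on the mean value (span 0.4, set with the data at hand), the brightest probe set of a gene, other brightness filters and thresholds, list members above the floor only, and the mean in place of the median of a list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.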

Results

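Macrophages grown from mouse bone marrow with M-CSF were compared between a genotype homozygous for the TB allele of MC4R and the same genotype carrying LysM. MC4R, the melanocortin 4 receptor, is a receptor coupled to cAMP signalling that is best known for its role in appetite control. In background terms, a TB allele of Mc4r is known as one whose transcription is blocked by a cassette that Cre recombinase can remove, and LysM, the gene Lyz2, is commonly used to drive Cre in myeloid cells; the labels do not spell out either. With that background, the comparison addresses how gene expression differs between macrophages with and without such a restoration; the arrays themselves do not show that it took place. Each group had 1 array, so no difference below has a replicate check, and the number of arrays limits the precision. Across 19505 genes the arrays correlated at r = 0.991, a correlation over genes, which are not independent replicates.

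The melanocortin receptor genes were dim on both arrays. Mc4r had a log2 value of 4.45 on the LysM(+) array and 4.57 on the TB/TB array, a difference of -0.12 that ranked at percentile 44.8 among the 500 genes nearest in mean value. Both values were under the brightness floor of 6.12 and within the range of the background control probe sets, so Mc4r expression was not distinguishable from background and the probe set gives no check of the genotype labels. Mc1r (4.07 and 3.89), Mc2r (4.42 and 4.14), Mc3r (4.76 and 5.40) and Mc5r (3.63 and 3.29) were also under the floor on both arrays. Lyz2, the lysozyme gene that marks myeloid cells, had values of 18.86 and 19.04, a 1.13-fold lower signal on the LysM(+) array near the top of the measured range. The Y-linked genes that were measured had a median difference of 0.17 over 6 genes, within the range of random lists (percentile 84.0). Of these 6 genes, 3 were above the brightness floor on both arrays. The 24 measured neighbours of Lyz2 on chromosome 10 had a median difference of 0.12 (percentile 92.3), with Nup107 and Mdm1, the latter under the floor on the TB/TB array, higher in LysM(+) by 0.67 and 0.61 on the log2 scale, and the 14 measured neighbours of Mc4r on chromosome 18 had one of -0.0077 (percentile 58.0).

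Genes of cell division dominated the largest differences, all in the direction of higher signal in LysM(+) macrophages. Among 10137 genes above the brightness floor, 1106 were at least 1.5-fold higher and 523 at least 1.5-fold lower in LysM(+), and at 2-fold these counts were 329 and 87. The balance was the other way among the 5573 probe sets above the floor that had no gene name here, of which 689 were at least 1.5-fold higher and 1069 at least 1.5-fold lower. For named genes it depended on brightness. With a brighter value from 6.12 to below 8, 330 were as much higher and 282 as much lower. Below the floor these counts were 255 and 552. Folds take the deposited values as log2, the scale that the method's name implies. The largest was Ube2c, a ubiquitin-conjugating enzyme that acts in mitotic exit, at 16.7-fold (log2 values 11.72 and 7.66), followed by the mitotic kinase Plk1 at 16.1-fold, the histone gene H3c8 at 14.8-fold and the mitotic kinesin Kif15 at 13.7-fold. The rest of the 15 largest were Ccna2, H1f1, the kinetochore gene Nuf2, Ccnb2, Rrm2, Pbk, Cdk1, H3c10, H3c11, Tcf19 and H2bc12, between 8.41-fold and 13.3-fold. Kif15, Cdk1 and Tcf19 lay below the brightness floor on the TB/TB array, so their folds rest on background-level signal there; Ccna2 and Pbk on that array, at 6.40, were above the floor but within the range of the background controls, which reached 6.81, so their folds are not exact either. Histone genes have near-identical copies whose probes can share signal. In the other direction the differences were smaller. Sorbs3, an adaptor protein of cell adhesion sites, was 4.44-fold lower in LysM(+), Dgat2, which makes triglycerides, 3.99-fold lower, Cnrip1 3.41-fold lower, the adhesion protein gene Tns1 3.35-fold lower and the salt-inducible kinase gene Sik1 3.31-fold lower. Fxyd2, Trp53i11, Aoah, Cpe, Csprs, Ephx1, Hpse, Usp18, Frmd4a and Slc13a5 completed the 15 lowest, between 2.51-fold and 3.09-fold lower; Aoah encodes an enzyme that inactivates lipopolysaccharide and Hpse encodes heparanase. Of these, Dgat2, Trp53i11, Cpe, Csprs, Frmd4a and Slc13a5 were below the brightness floor in LysM(+), and Sik1, at 6.65, was within the background control range. Csprs and Slc13a5, at 6.13 and 6.28 on the TB/TB array, were within that range on both arrays, so their folds are not exact. The same holds for Mdm1, Abcg4, Cxcr2, Mgl2, Mmp9, Treml4, Dusp4 and Col6a1, named elsewhere in this report.

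The counts contain array-to-array noise of unknown size. In all, 16.1% of genes above the floor differed by at least 1.5-fold. In data simulated with the observed spread, 12.5% of unchanged genes did so. That simulated share is over genes whose mean value reached the floor, with normal noise, so the shares are not directly comparable. Of 1410 olfactory and vomeronasal receptor genes, most of which are silent outside sensory tissue, 10.0% differed by at least 1.5-fold with no floor applied. The brighter value of 60 of them reached the floor, 34 on both arrays; of the 60, 1 (Olfr1087, under the floor on the TB/TB array) was at least 1.5-fold higher and 13 were at least 1.5-fold lower. That share, 23.3%, is raised by the floor itself, which a gene near it can reach through the difference. This receptor set and Olfr1087 were chosen after the data were seen.

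**Figure D1:**
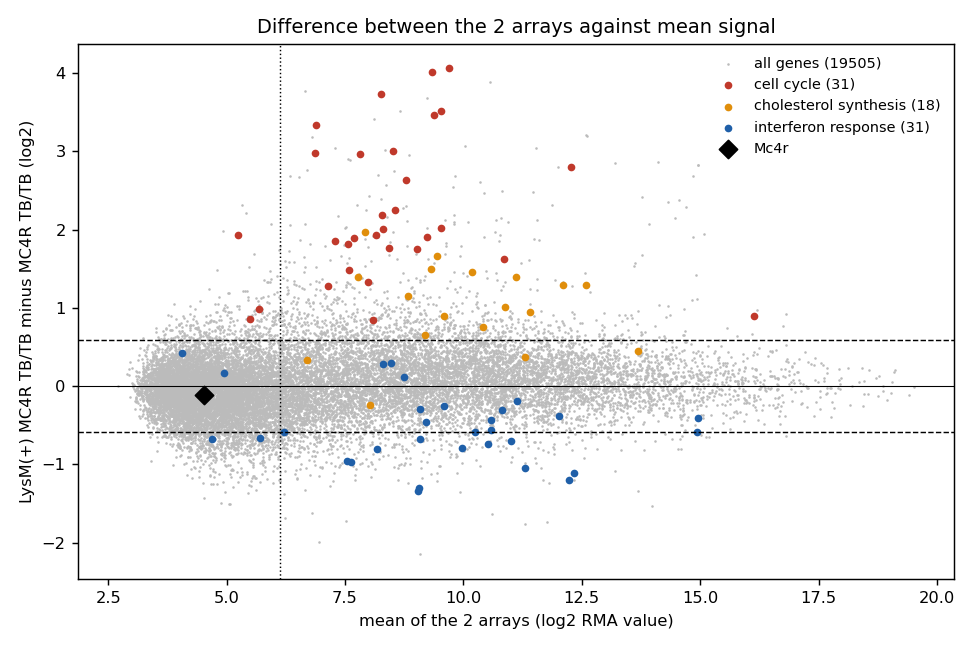
Difference between the arrays (LysM(+) MC4R TB/TB minus MC4R TB/TB, log2, vertical axis) against the mean of the 2 arrays (log2 RMA value, horizontal axis) for 19505 genes, 1 point per gene, with 1.5-fold marked by dashed lines and the brightness floor of 6.12 by a dotted line. All 31 cell cycle genes and 17 of 18 cholesterol synthesis genes lie above 0, 26 of 31 interferon response genes lie below it, and Mc4r lies at -0.12 at background-level signal.

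Cell cycle genes were higher in LysM(+) macrophages as a group. In this and the other lists, a member was counted at 1.5-fold only if its brighter value reached the floor. All 31 measured members of the list had higher values, 30 of them by at least 1.5-fold above the floor, and the median difference was 1.93, or 3.82-fold, against a range of -0.09 to 0.24 for the central 95% of random lists. Besides Ube2c and Plk1, the mitotic cyclin genes Ccna2 and Ccnb2 were 13.3-fold and 11.4-fold higher. The smallest difference in the list was 0.84. Neutrophil genes were higher in the same array (median difference 0.40), while the haematopoietic progenitor list had a median difference of 0.10, within the random range. Only 2 of the 9 measured progenitor genes reached the floor, so that median says little about progenitors. Apoptosis and p53 target genes had a median difference of -0.06 (percentile 10.3), with the survival gene Bcl2 1.82-fold higher and Bcl2a1a 1.61-fold lower in LysM(+).

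Genes of cholesterol synthesis formed the list with the next largest difference. Of 18 measured members, 14 were at least 1.5-fold higher in LysM(+), 0 were as much lower, and the median difference was 1.08, or 2.11-fold (random range -0.10 to 0.30). Sqle, squalene epoxidase, was 3.93-fold higher, Idi1 3.16-fold, Hsd17b7 2.81-fold and Msmo1 2.74-fold. Fatty acid synthesis genes stood apart in the same direction with a median difference of 0.38 (percentile 98.8) over 11 members, of which 4 were at least 1.5-fold higher: the desaturase gene Fads2 at 3.46-fold, the elongase genes Elovl6 and Elovl5 at 2.38-fold and 1.72-fold, and Fasn, fatty acid synthase, at 2.31-fold. Elovl6 was under the floor on the TB/TB array, so its fold rests on background-level signal. Genes of cholesterol efflux and LXR targets did not stand apart: their median difference was -0.09 (percentile 6.31) over 16 members, and Abcg4, at 1.80-fold lower and under the floor in LysM(+), was the sole member past 1.5-fold. By its mean, -0.14, this list lay below the random range (percentile 1.21). The efflux transporter genes Abca1 and Abcg1, named after their values were seen, differed by -0.24 and -0.39. Lipoprotein and lipid uptake genes went both ways, with a median difference of -0.05 (percentile 12.7) over 17 members. The fatty acid binding protein gene Fabp4 was 2.30-fold lower in LysM(+), whereas lipoprotein lipase, Lpl, was 1.89-fold higher and the scavenger receptor genes Colec12 and Scarf1 were 1.78-fold and 1.66-fold higher. Fatty acid oxidation and PPAR target genes had a median difference of 0.06 (percentile 50.6), with Slc25a20 1.53-fold higher.

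Interferon response genes were lower in LysM(+) macrophages. Of 31 measured members, 14 were at least 1.5-fold lower, 0 were as much higher, and the median difference was -0.59 (random range -0.09 to 0.23). Usp18, a negative regulator of interferon signalling, was 2.53-fold lower, the antiviral gene Rsad2 2.46-fold, Ifit3 2.29-fold and Xaf1 2.16-fold. Antigen presentation genes went the same way. MHC class II presentation genes had a median difference of -0.29 (percentile 0.07) over 14 members, of which 4 were at least 1.5-fold lower: Ciita, the master regulator of class II expression, at 1.91-fold, H2-DMa at 1.78-fold, H2-Eb1 at 1.76-fold and H2-Ab1 at 1.57-fold. MHC class I presentation genes had a smaller median difference of -0.12 (percentile 1.86) over 16 members, with H2-T23 and the proteasome activator gene Psme2 1.89-fold and 1.59-fold lower, Tap1 and Tap2 1.33-fold and 1.30-fold lower, and Erap1, named after its value was seen, 1.51-fold higher. H2 genes belong to a family of similar sequences whose probes can share signal.

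**Figure D2:**
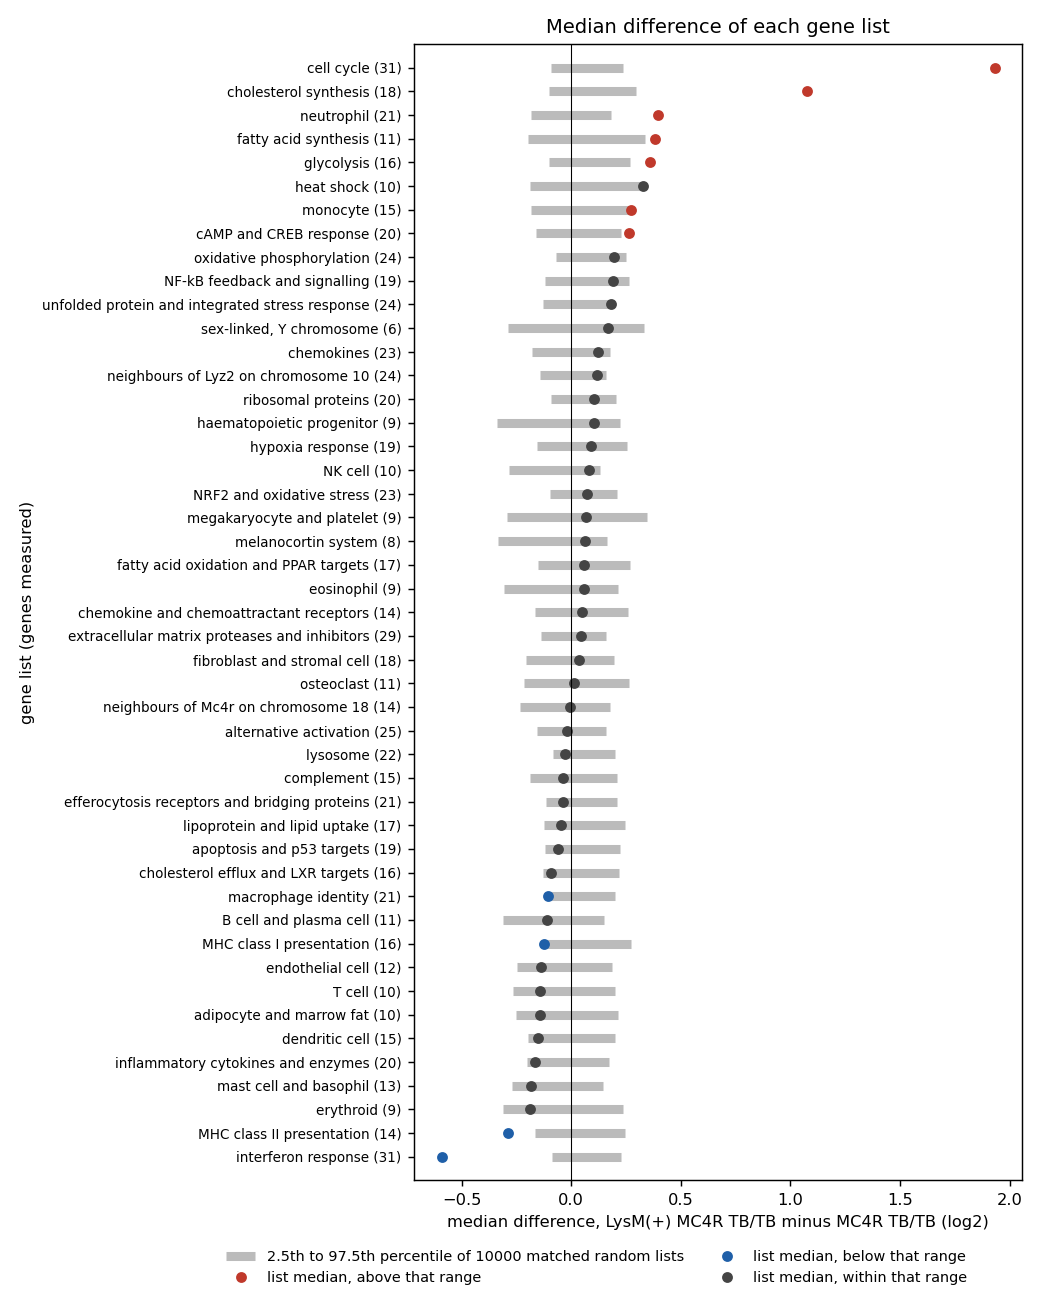
Median difference of each of 47 gene lists (LysM(+) MC4R TB/TB minus MC4R TB/TB, log2, horizontal axis), as 1 point per list with the number of genes measured in brackets, over a grey bar that spans the central 95% of 10000 random lists matched on mean expression. Cell cycle (1.93) and cholesterol synthesis (1.08) lie far above their bars and interferon response (-0.59) far below, while 36 lists lie within theirs.

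Inflammatory cytokines and enzymes had a median difference of -0.16 (percentile 6.02) over 20 members. Tnf was 2.43-fold higher in LysM(+), while the acute-phase gene Saa3 and the itaconate-making enzyme gene Acod1 were 1.63-fold and 1.52-fold lower; over the 12 members above the brightness floor the median difference was -0.41, at percentile 0.09, below the random range. Chemokine genes had a median difference of 0.12 (percentile 90.8) over 23 members, of which 6 above the floor were at least 1.5-fold higher, including the platelet-type chemokine genes Ppbp and Pf4 at 4.46-fold and 2.35-fold, Ccl6 at 2.11-fold and Cxcl2 at 1.63-fold. No chemokine gene above the floor was as much lower (0 genes), but Ccl8, under the floor on both arrays and named after its value was seen, differed by -1.09. The chemokine list lay above the random range with loess (percentile 97.7) and by its mean (percentile 99.0). Chemokine and chemoattractant receptor genes had a median difference of 0.05 (percentile 53.9), with Cx3cr1, the fractalkine receptor, 3.74-fold higher, Ccr3 2.28-fold, Cxcr2 1.63-fold and C5ar1 1.56-fold, and Ccrl2, named after its value was seen, 1.51-fold lower; Cxcr2 was under the floor on the TB/TB array. NF-kB feedback and signalling genes had a median difference of 0.19 (percentile 89.4), with Tnip3 2.03-fold and Nfkbib 1.80-fold higher. Alternative activation genes had one of -0.02 (percentile 40.1), with Pdcd1lg2, Mgl2 and Clec10a 2.19-fold, 1.83-fold and 1.54-fold lower and Il10 1.56-fold higher; in LysM(+) Mgl2 was under the floor and Pdcd1lg2, at 6.20, within the background control range. Extracellular matrix proteases and inhibitors, which include enzymes that degrade the vessel wall matrix, had a median difference of 0.05 (percentile 68.8) over 29 members. Here 4 members were at least 1.5-fold higher in LysM(+): Plau, the urokinase gene, at 4.43-fold, Mmp9 at 2.21-fold, Adam8 at 2.16-fold and Mmp8 at 1.98-fold. None of the 29 was as much lower (0 genes). Mmp9 was below the brightness floor on the TB/TB array and, at 6.45, within the background control range in LysM(+). Complement genes had a median difference of -0.04 (percentile 30.3), with C5ar2 1.73-fold higher.

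The 21 measured macrophage identity genes all reached the brightness floor and none differed by 1.5-fold (0 genes), with a median difference of -0.11 (percentile 1.76); the lowest were Mertk, an apoptotic cell receptor, at 1.49-fold, Mpeg1 at 1.31-fold, and Fcgr3 and Lgals3 at 1.30-fold lower. That list no longer stood apart after quantile normalization (percentile 3.16) or loess (percentile 2.88). Neutrophil genes were higher in LysM(+), with a median difference of 0.40 (random range -0.18 to 0.18) over 21 members; 6 were at least 1.5-fold higher and 0 as much lower, and Csf3r and Mpo, named after their values were seen, were the members with the lowest differences above the floor, at -0.57 and -0.30. The granule protein genes Ltf and Elane were higher by 1.38 and 1.18 on the log2 scale, Retnlg by 1.32 and Mmp9 by 1.15. Elane and Retnlg on the TB/TB array, at 6.46 and 6.29, were within the background control range, and Mmp9 was within it on both arrays. Of the 21 neutrophil genes, 11 were above the floor on both arrays and 5 also stood in other lists. Monocyte genes had a median difference of 0.27 (percentile 97.8) over 15 members, led by Cx3cr1 at 3.74-fold, with Treml4 (under the floor on the TB/TB array), Plac8 and Ly6c1 1.49-fold, 1.39-fold and 1.32-fold higher and Itgal, named after its value was seen, 1.93-fold lower; this list fell within the random range after quantile normalization (0.20, percentile 93.8) or loess (0.18, percentile 92.6), over members above the floor (0.27, percentile 96.1) and by its mean (0.14, percentile 76.5). The 13 lists for other cell types, from T cells to osteoclasts and haematopoietic progenitors, had median differences between -0.19 and 0.10, all within the random range. Members past 1.5-fold and above the floor in these lists were Col6a1 (under the floor on the TB/TB array) and Tnfrsf11a, 1.73-fold and 1.81-fold higher, and Cd28, Hdc, Tfrc, Vwf, Col1a2, Postn and Dcstamp, between 1.51-fold and 1.96-fold lower, besides genes already given. Several of these 13 lists were mostly dim, so their medians cannot show whether such cells differed between the cultures. The brighter value reached the floor for 0 of 10 NK cell genes and 1 of 13 mast cell and basophil genes. It did so for 2 of 11 B cell and plasma cell genes and 2 of 9 in the eosinophil, erythroid and progenitor lists each. The fibroblast and stromal cell (12 of 18) and osteoclast (8 of 11) lists were less dim.

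**Figure D3:**
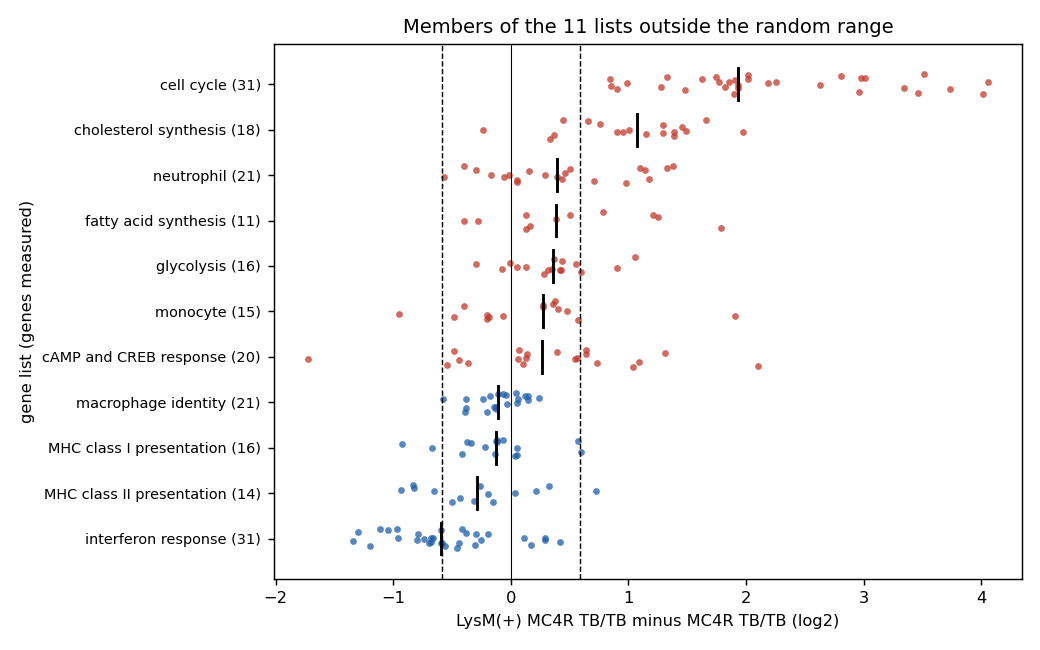
Difference of each measured member (1 point per gene, LysM(+) MC4R TB/TB minus MC4R TB/TB, log2, horizontal axis) in the 11 lists whose median lay outside the range of random lists, with the list median as a black bar and 1.5-fold as dashed lines; vertical scatter within a list carries no meaning. Cell cycle members lie between 0.84 and 4.06, and macrophage identity members between -0.57 and 0.24.

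Among signalling and metabolic groups, cAMP and CREB response genes stood apart with a median difference of 0.26 (percentile 99.1) over 20 members, of which 6 were at least 1.5-fold higher and 1 as much lower. The immediate-early gene Fos was 4.29-fold higher in LysM(+), the phosphodiesterase gene Pde3b 2.49-fold, and the phosphatase genes Dusp4 and Dusp1 2.13-fold and 2.05-fold, whereas Sik1, a known CREB target, was 3.31-fold lower. Dusp4 was under the floor on the TB/TB array and, at 6.22, within the background control range in LysM(+), so its fold rests on background-level signal. By any amount, 15 of the 20 members were higher and 5 lower. Fos, Dusp4 and Dusp1 respond to growth factors as well as to cAMP, so the list does not show that cAMP signalling differed. Glycolysis genes had a median difference of 0.36 (percentile 99.8) over 16 members, with Pdk1 2.08-fold, the glucose transporter gene Slc2a1 1.87-fold, Pgk1 1.51-fold and Slc16a3 1.47-fold higher; by its mean (0.34) the list was at percentile 97.0, within the random range. Heat shock genes (median 0.33, percentile 97.2), unfolded protein and integrated stress response genes (0.18, percentile 96.8), oxidative phosphorylation genes (0.19, percentile 89.8), hypoxia response genes (0.09, percentile 67.8), NRF2 and oxidative stress genes (0.07, percentile 58.1) and ribosomal protein genes (0.10, percentile 73.1) did not stand apart. In these lists the amino acid and one-carbon enzyme genes Asns, Mthfd2 and Psat1 were 2.98-fold, 2.32-fold and 2.07-fold higher, Dnajc3 1.73-fold, Srxn1 2.57-fold, Cycs 1.87-fold, and the chaperone genes Hsp90aa1 and Hsph1 1.88-fold and 1.57-fold. Lysosome genes (-0.03, percentile 12.3) and efferocytosis genes (-0.04, percentile 14.2) were within the random range, with Atp6v1h 1.56-fold and Itgav 1.87-fold higher.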

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

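No paired analysis was possible because each group had 1 array. No array could be left out for the same reason, and without detection calls the signal over background limits what can be said of dim genes. The median difference over all genes stayed between -0.0062 and 0.0082 under every scaling, and the loess trend moved single genes by at most 0.10. Between the normalizations the share of higher among counted genes ranged from 61.7% (loess: 943 higher, 585 lower) to 69.3% (centring: 1139 and 505); loess kept 905 of the 1106 higher and 480 of the 523 lower genes. The counts moved by more than 1.5 times with the filter and the threshold: 556 higher and 158 lower with the brighter array at or above the 75th percentile, 329 and 87 at 2-fold, 231 and 53 beyond 3 robust SDs of the 500 nearest genes, and, for the lower count alone, 1075 with no filter on dim genes (1361 higher). Without that filter 55.9% of counted genes were higher, with the 75th percentile filter 77.9%, at 2-fold 79.1% and beyond 3 robust SDs 81.3%. Cell cycle, cholesterol synthesis, fatty acid synthesis, cAMP and CREB response, neutrophil, interferon response and both MHC lists stood apart in the same direction under all 6 alternatives for lists. Where a list median moved by more than 1 SD of its random lists, a tolerance set with the data at hand, the value over members above the floor was 0.39 for cAMP and CREB response, 0.10 for lipoprotein and lipid uptake, -0.41 for inflammatory cytokines and enzymes, 0.23 for chemokines, 0.19 for chemokine and chemoattractant receptors, 0.17 for extracellular matrix proteases and inhibitors, -0.43 for MHC class II, 0.51 for neutrophil, -0.13 for fibroblast and stromal cell, -0.25 for endothelial cell, 0.017 for adipocyte and marrow fat and 0.17 for the neighbours of Mc4r. As a mean it was -0.041 for inflammatory cytokines, 0.26 for chemokines and for chemokine receptors, 0.15 for matrix proteases, 0.14 for monocyte, 2.23 for cell cycle and 0.35 for megakaryocyte and platelet, and after loess 0.10 for oxidative phosphorylation. Some lists that did not stand apart did so under an alternative: chemokines with loess (percentile 97.7) or the mean (99.0), heat shock with quantile normalization or loess (97.6), and by their means the stress response (97.7), LXR target (1.21) and erythroid (1.41) lists. The cause of these changes was not tested. None of the genes named in the report or in this section, including those named after their values were seen, changed sign under the 4 scaling and probe set alternatives. These alternatives shift values little, so unchanged signs were close to assured. They do not bear on whether a difference would recur in other cultures, and some of these genes, such as Mc4r, were at background level.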

Other observations

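The gene lists that open this part, the genes named from them, and the use of any value in it to weigh an explanation were chosen after the data were seen; the loess alternative and the progenitor, neutrophil, macrophage identity and LXR target lists had been fixed beforehand. Replication-dependent histone genes were higher in LysM(+) macrophages: of 53 measured, 44 above the floor were at least 1.5-fold higher and 0 as much lower (H2bc1, under the floor on both arrays, differed by -0.62), with a median difference of 2.12 (4.36-fold; random range -0.03 to 0.19), although near-identical copies such as H3c14 and H3c15, which had equal values on both arrays, are not independent. Genes of the S phase had a median difference of 1.05 (2.07-fold, 39 genes) and genes of the G2 and M phases one of 1.59 (3.01-fold, 50 genes). These lists overlap the cell cycle list of the report by 8 and 15 genes and are not independent of it; without those genes their medians were 0.99 and 1.33. Genes of serine, one-carbon and nucleotide synthesis had a median difference of 0.67 over 24 genes, 13 of them at least 1.5-fold higher, among them Tyms at 4.04-fold and Rrm1 at 3.63-fold, and Psph 1.59-fold lower; 3 of the 24 stood in another of these lists. Cell cycle, S phase, G2 and M phase and histone genes together made up 123 of the 1106 genes at least 1.5-fold higher (11.1%), 104 of the 329 genes at least 2-fold higher (31.6%) and 0 of the 87 at least 2-fold lower, so 225 genes with 2-fold higher signal lay outside these lists. FoxO target and quiescence genes went the other way, with a median difference of -0.28 over 25 genes (random range -0.10 to 0.24), 7 at least 1.5-fold lower, led by Deptor at 2.36-fold and Gadd45a at 2.19-fold, and Bcl6 2.05-fold higher. Ribosome biogenesis and MYC target genes had a median difference of 0.24 (percentile 96.4), within the random range.

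For the first pattern, the higher level of cell cycle genes, an intensity trend between the arrays left by the normalization is argued against, since the list median after loess was 1.92, against 1.93 before. One hypothesis is stronger or more recent growth factor signalling in the LysM(+) culture at harvest, such as a difference in cell density or M-CSF supply: it predicts higher immediate-early and ERK feedback genes and lower FoxO targets. The immediate-early list had a median difference of 0.19 (percentile 94.7), within the random range. Its mean difference was 0.41, and of its 26 members 9 were at least 1.5-fold higher and 0 as much lower. The FoxO list was at percentile 0, but it also holds quiescence genes, which could be lower in any culture with more dividing cells. That list therefore does not single out growth factor signalling, and this hypothesis stays open. Stem or progenitor cells left in the culture stay open too, because only 2 of the 9 progenitor genes reached the brightness floor (list median 0.10). Neutrophil genes, some of which dividing granulocyte precursors express, were higher in the same array (median 0.40, percentile 100). Csf3r and Mpo differed by -0.57 and -0.30, and the list does not separate dividing precursors from mature cells. The genotype is confounded with the culture and the array, so it remains an open, untested explanation.

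The second pattern is the lower level of interferon response genes. It was not removed by loess, after which the median was -0.59, which argues against an intensity trend. A lower share of macrophages in the LysM(+) culture that lowered both lists alike predicts macrophage genes as low as the interferon genes. The 21 macrophage identity genes had a median difference of -0.11 (SD over genes 0.21). That was 0.30 to 0.72 above that of the 27 interferon genes above the floor in the central 95% of 10000 resamplings of the genes. For the 11 macrophage genes with a mean value under 16, the median was 0.054 (SD 0.22) and the range 0.33 to 0.85. This limit was meant to keep out the brightest probe sets, where signal can be compressed. The values argue against such an equal lowering only. Resampling genes that are regulated together does not measure differences between cultures. The macrophage list itself stood apart lower (percentile 1.76), though not after quantile normalization or loess. Neutrophil genes were higher (median 0.40, percentile 100), so a changed cell mix stays open. A difference between the cultures in exposure to interferon and a genotype effect were not tested and cannot be separated with 1 array per group.

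The third pattern is the higher level of cholesterol synthesis genes, whose median was 0.99 after loess, against an intensity trend. A candidate explanation is lower sterol content of the LysM(+) cells, which would lower LXR target genes at the same time. The LXR target list was at percentile 6.31, with a median difference of -0.09, within the random range, but by its mean, -0.14, it was at percentile 1.21, below that range; with the call resting on that choice, the values do not decide it. The genotype again remains open.

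The 4 bacterial and phage hybridization controls, which include a probe set for a cre spike-in and so do not report on a Cre transgene, were all lower on the LysM(+) array, with log2 differences from -0.25 to -0.21, while the 4 other spike-in controls went both ways (dap -0.24, thr -0.21, phe 0.0067, lys 0.19) and the background controls differed by at most 0.094.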
